A study of Homo sapiens with 12 samples.

How the data were processed

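Total RNA from SKBR3 cells, a human breast cancer cell line with amplified ERBB2, was labelled with biotin and hybridised to Illumina human-6 v2 expression beadchips, per the labels' protocols. Serum was withdrawn before transfection, the cells were transfected for 30 h with Fugene, a lipid reagent, and each treatment lasted 1 h, per the labels' protocols. The labels give 4 groups of 3 arrays lettered A, B and C: control-transfected cells left uninduced, control-transfected cells with 10 µM hydroxytamoxifen (OHT), control-transfected cells with 1 µM estradiol (E2), and cells transfected with a GPR30 antisense and given 10 µM OHT. What the control transfection carried and what kind of antisense was used are not given in the sources used here. An uninduced antisense group was not analysed here, so an effect of the antisense on uninduced cells and one on the response to OHT could not be separated.

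The deposited file of each array holds, per the file headers, an average signal intensity for each of 48701 probes on a linear scale, with the number of beads read, a standard error over beads and a detection p-value. These intensities were neither normalized between arrays nor background-subtracted by the authors, as far as the values show, and the scanner software and its version are not given in the sources used here. The authors' deposited value table was also used, as an alternative. Its intensities share the same quantiles in all 12 columns, with column medians from 78.4 to 78.6, so they had been quantile normalized on a linear scale, and they were put on the log2 scale here. Each column of that table ranked 48693 probes as the matching array did, with a Spearman correlation of 0.978 to 0.982, against at most 0.846 with any other array. However, 1534 probes (3.15%) lay more than 0.3 log2 units away from the common curve on all 12 arrays, and what the authors did to them is not given in the sources used here.

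The intensities were corrected for background with limma 3.58.1 in R 4.3.3, with the function nec, which infers the negative controls from the detection p-values, and an offset of 16. They were then quantile normalized and put on the log2 scale. Probes with a detection p under 0.05 on at least 3 of the 12 arrays were kept, which left 19645. Gene symbols came from a platform annotation table that lists 23716 of the probes, 23681 of them with 1 symbol and 35 with several, and 24985 probes of the array files have no gene in that table. Of the probes with 1 symbol, 23645 were matched by Entrez ID to a gene table of the GRCh38.p14 assembly, used for names only. No coordinates are printed, since no build is named for the array. A gene was represented by its kept probe with the highest mean log2 signal, which gave 11729 genes, 1451 of them with more than 1 kept probe. A further 6107 kept probes had no single symbol and were tested separately. Listed genes without an annotated probe were not analysed here.

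One mean per group was fitted to all 12 arrays with limma's lmFit and eBayes, without a trend, so that the groups shared one estimate of the spread with 6.59 prior degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the 11729 genes of a comparison, and a gene was called at an adjusted p under 0.05. Signed log2 values run from the second-named to the first-named group (OHT minus uninduced, E2 minus uninduced, antisense with OHT minus OHT), given with the standard error (SE) of the difference, and group levels are given with the standard deviation (SD) over 3 arrays. Where a probe was above background on no array of the dimmer group, the fold is a lower bound, computed as the brighter group's mean against, per array, the higher of the probe's own value and the lowest normalized signal among probes above background. The 23 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01 wherever 3 or more members were measured, and again with an estimated correlation and with fry, with adjustment over the lists of a comparison. The same genes can sit in several lists: ATF3, FOS, DUSP1 and NR4A2 each count in more than 1.

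The groups, tests, gene lists and naming rule, and all alternatives except those said to have been added later, were fixed before the data were examined. The naming rule took, for each main comparison, the 10 largest rises and 10 largest falls among called genes whose 3 arrays of one group lay wholly above or below those of the other, up to 4 members of each list with the smallest p, and 11 genes named in any case (GPER1, ESR1, ESR2, ERBB2, FOS, EGR1, JUN, ATF3, CCN1, CCN2 and DUSP1). For OHT against E2 it took the 5 genes with the smallest p. Several of the 11 genes are known from earlier work on GPR30, so their changes are not an independent test. The antisense median of the genes that rose with E2, and of no other set, was set against 10000 lists of unresponsive genes matched on mean signal. These genes were called in none of the 3 main comparisons, and this check was added after the data were seen. The correlation of the OHT and E2 changes was set against 100 simulations without effects that shared the uninduced arrays.

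Total signal per array ran from 9643352 to 13275469, 16220 to 17935 probes (33.3% to 36.8%) were above background, and the median probe was read on 39 or 40 beads. Arrays of one group correlated at 0.993 to 0.997 on average. No replicate pair shared identical signals, and the variance between replicates was 1.99 to 5.27 times the bead noise over 6667 bright probes. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these arrays, which may be technical, and the number of arrays limits the precision. The limma fit was tested for OHT against uninduced on normalized log2 values of 11729 genes simulated with independent normal noise. Background correction, normalization, filtering, probe choice and beadchip or position differences were not simulated. The fit recovered 90.4% of 50 genes changed 1.5-fold, 99.6% of 50 changed 2-fold and 100% of 50 changed 3-fold, over 5 draws. It made 4.7% false calls and recovered only 18% of 50 genes given a smaller change.

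The 6 uninduced and OHT arrays lie on one beadchip and the 6 E2 and antisense arrays on the other. The comparison of OHT with uninduced therefore lies within a beadchip, while E2 against uninduced, OHT against E2 and both antisense comparisons cross the beadchips, and since each group lies on 1 beadchip no fit with the beadchip as a block was possible for them. On their beadchips, uninduced and E2 arrays lie at positions A to C, and OHT and antisense arrays at positions D to F. In OHT against uninduced and in antisense against E2, a position difference therefore cannot be told apart from the difference between the groups. Antisense with OHT against E2, which lies within a beadchip, is given beside the antisense results as an alternative added after the data were seen, as were fits without antisense arrays B and C. The alternatives set out beforehand were normexp without control probes and an offset of 50 (the other background model), no background correction, other normalizations (a shift to a common median, cyclic loess) and filters, the authors' value table, a mean over a gene's probes, an empirical Bayes prior with trend and robust estimation, array weights, a fold minimum of 1.5, fits to the compared groups alone, the replicate letter as a block and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.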

Results

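Gene expression was measured on 12 one-colour beadchip arrays of SKBR3 cells, 3 in each of 4 groups. The study set out to find transcripts regulated by estradiol and by hydroxytamoxifen through GPR30, the product of GPER1, a membrane G protein-coupled receptor that binds estrogens. E2 is the steroid estrogen, and OHT is a nonsteroidal triphenylethylene that blocks the nuclear estrogen receptors in breast cells. The doses differed, at 10 µM OHT and 1 µM E2, and the treatments lasted 1 h. Total signal ranged from 9643352 to 13275469 per array, and 11729 genes were above background on enough arrays to be tested.

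The antisense targets GPER1, whose mRNA was not measurable on these arrays. Both GPER1 probes were above background on 0 of 12 arrays, with detection p between 0.216 and 0.767 and signals between 40.5 and 49.6. Antisense minus OHT was 0.046 ± 0.054 log2 (SE) for one probe and 0.0027 ± 0.0635 for the other, at background, so these arrays do not show whether the antisense lowered the transcript. ESR1, which encodes the nuclear estrogen receptor alpha, was above background on 0 of 12 arrays. ESR2, which encodes the beta receptor, was above background on 7 of 12 arrays at a mean log2 signal of 4.61 to 4.87 per group, and no comparison called it (E2 minus uninduced 0.21 ± 0.13, adjusted p = 0.751). ERBB2, the receptor gene amplified in this line, differed by 0.11 with OHT (adjusted p = 0.951), by -0.11 with E2 (adjusted p = 0.907) and by -0.28 with the antisense (adjusted p = 0.363).

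The first question was which transcripts changed within 1 h of OHT. CCN2, which encodes a secreted matricellular protein, rose 11.2-fold, from a log2 signal of 7.83 ± 0.11 (SD, n = 3) to 11.32 ± 0.31, a difference of 3.49 ± 0.16 (SE, adjusted p = 5.7e-09). The AP-1 subunit genes FOSB and FOS rose 5.55-fold (2.47 ± 0.14) and 4.82-fold (2.27 ± 0.13), and the stress-responsive transcription factor ATF3 rose 5.25-fold (2.39 ± 0.11). EGR1, a zinc finger transcription factor of the serum response, rose 4.24-fold (2.08 ± 0.09, adjusted p = 5.1e-09). RASD1, a Ras-related GTPase, TNF, an inflammatory cytokine, and EDN2, a precursor of an endothelin peptide, rose 4.08-fold, 3.99-fold and 2.81-fold, with adjusted p-values from 4.85e-08 to 1.52e-05. In all, 65 of 11729 genes changed, 61 up and 4 down, and 43 of them, all up, changed at least 1.5-fold. An unadjusted p under 0.05 was found for 868 genes, called ones included. All 65 had their 3 arrays per group wholly apart, against 14.3% of all genes and the 10% that chance gives. The calls select for this on the same arrays, so it is no separate support for them. The 4 falls were small: MTRFR by -0.50 ± 0.09, MS4A7 by -0.48 ± 0.10, ANKRD22 by -0.43 ± 0.09, and CAMK2N2 at least 1.23-fold, since CAMK2N2 was above background on 0 of 3 OHT arrays. Of the 65 calls, 41 held with each of the 6 arrays left out in turn, all of them rises, and none of the falls did. With arrays shifted to a common median instead of quantile normalized, 33 genes were called, 23 up and 10 down, 25 of the 65 remained, and the median of all genes moved to -0.20, and DDIT4, ERRFI1, TNFAIP3, FHL2, SRF, ID3, IRF1, TGIF1, ANKRD22 and CAMK2N2 lost their calls. The falls of ANKRD22, CAMK2N2 and MS4A7 were also lost with the other background model, without background correction and from the authors' value table.

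By fixed list, 13 of the 21 measured immediate early transcription factors rose with OHT, 0 fell and 8 did not pass (15 rose when adjusted over the list alone), with a median of 0.66. FOSB, EGR1 and NR4A2, an orphan nuclear receptor (1.98-fold), were among them, as was JUN, another AP-1 subunit (1.91-fold). Among 17 feedback inhibitors of MAP kinase signalling, 5 rose and 12 did not pass (9 rose when adjusted over the list alone). They included the phosphatases DUSP1 (2.75-fold), DUSP5 (2.21-fold) and DUSP4 (1.92-fold), and the EGFR inhibitor ERRFI1 (1.46-fold). RGS16, which shortens G protein signalling and is in no list, rose 2.67-fold. Among 13 CREB and cyclic AMP targets 6 rose and 7 did not pass (7 rose when adjusted over the list alone), FOS, ATF3, DUSP1 and NR4A2 among them. Of 15 genes of the integrated stress and unfolded protein response 6 rose and 9 did not pass (9 rose when adjusted over the list alone), among them DDIT3, a pro-apoptotic transcription factor (2.55-fold), PPP1R15A, a subunit of the phosphatase that reverses translation arrest (2.37-fold), and DDIT4, an mTOR inhibitor (1.67-fold). Of 13 NF-kB targets and cytokines 4 rose and 9 did not pass (7 rose when adjusted over the list alone): TNF, the inhibitor genes TNFAIP3 (1.81-fold) and NFKBIA (1.75-fold), and CXCL8, which was above background on 0 of 3 uninduced arrays and rose at least 1.24-fold. Of 12 matricellular genes and YAP/TEAD targets 3 rose and 9 did not pass (4 rose when adjusted over the list alone), namely CCN2, CCN1 (2.36-fold) and EDN1, an endothelin precursor (1.86-fold), so the list's mean was 0.50 but its median 0.02. Limma's camera called these 6 lists upward, with adjusted p-values from 7.1e-50 to 2.5e-06.

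Camera called a further 2 lists upward with OHT, and neither held with an estimated correlation. Of 12 TGF-beta and BMP targets 2 rose, the transcriptional regulators TGIF1 (1.35-fold) and ID3 (1.56-fold), and 10 did not pass (adjusted over the list alone, 3 rose and 1 fell), with an adjusted p of 0.00093 that became adjusted p = 0.055 with an estimated correlation. Of 12 SRF cytoskeletal targets 2 rose, SRF itself, which encodes the serum response factor (0.59 ± 0.09), and FHL2, a LIM-domain cofactor (0.58 ± 0.09), and 10 did not pass (2 rose when adjusted over the list alone). That list had an adjusted p of 0.031, which became adjusted p = 0.11 with an estimated correlation. The other 6 calls held with it. Of the genes named from these lists, CXCL8 lost its call with any 1 of the 6 arrays left out, ID3 kept it without 2 of them and TGIF1 without 3, and CXCL8 and ID3 were not called when dim probes were kept. Another probe of TGIF1 was at 0.24 with OHT (limma, unadjusted p = 0.093).

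The second question was which transcripts changed within 1 h of E2. CCN2 rose 11.5-fold (3.53 ± 0.16 log2, SE; n = 3 arrays per group; adjusted p = 7.3e-09), to a log2 signal of 11.36 ± 0.12 (SD). FOS rose 6.23-fold (2.64 ± 0.13), FOSB 5.12-fold (2.36 ± 0.14), ATF3 4.88-fold (2.29 ± 0.11) and EGR1 4.84-fold (2.28 ± 0.09, adjusted p = 1.4e-09). RASD1 rose 3.82-fold, TNF 3.6-fold, DUSP1 3.13-fold and RGS16 2.54-fold. In all, 61 genes changed, 57 up and 4 down, 38 of them at least 1.5-fold, all 38 up, and 959 genes had an unadjusted p under 0.05. The 3 arrays per group lay wholly apart for all 61 called genes, which their calls favour, for 15.8% of all genes, and for 10% by chance. The falls were TICAM2-AS1 (-0.57 ± 0.10, above background on 1 of 3 E2 arrays, and lost with the other background model, without background correction and from the authors' value table), RIMBP3 (-0.50 ± 0.09), TNRC6C, a component of the microRNA silencing complex (-0.47 ± 0.08), and FZD4, a Wnt receptor (-0.40 ± 0.08). Another probe of TNRC6C was at -0.09 with E2 (limma, unadjusted p = 0.472). Of the 61 calls, 35 held with each array left out in turn, none of them a fall, and the count was 40 without uninduced array A and 39 without uninduced array C. Every E2 array lies on the other beadchip from the uninduced arrays. A beadchip difference would also enter the antisense arrays, which share the E2 beadchip, and there 24 of the 57 genes that rose were called lower with the antisense than with E2. FOS was at 5.29 in them against 7.83 with E2 and 5.19 uninduced, and DUSP1 at 7.85 against 9.98 and 8.33. For these 24 genes this bears against a beadchip difference only if the antisense had not lowered their uninduced level, which was not measured. The 57 genes were also chosen on the same E2 arrays, which favours such calls. For the other 33 genes that rose and the 4 that fell, taken one by one, and for any rise still present with the antisense, a beadchip difference and E2 cannot be told apart. Antisense minus OHT crosses the same beadchips with other arrays, and across 11632 genes called in none of the 3 comparisons, which are not independent replicates, it correlated with the E2 change at r = -0.0059. The count was 106 with the other background model (82 up, 24 down), 99 without background correction (80 up, 19 down), 105 from the authors' value table (79 up, 26 down), 103 with the trend and robust prior, 95 with array weights and 38 with the median shift, which kept 35 of the 61 calls and ended those of DDIT4, ERRFI1, NFKBIA, FHL2, SRF, TGIF1, THBS1, FZD4, RIMBP3 and TNRC6C.

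Of the 21 immediate early transcription factors 12 rose with E2, 0 fell and 9 did not pass (15 rose when adjusted over the list alone), with a median of 0.69, and JUN and NR4A2 rose 1.90-fold and 1.85-fold. Among the 17 MAP kinase feedback inhibitors 5 rose and 12 did not pass (8 rose when adjusted over the list alone), DUSP5 (1.87-fold) and DUSP4 (1.66-fold) among them. Of the 13 CREB and cyclic AMP targets 6 rose and 7 did not pass (8 rose when adjusted over the list alone). Of the 15 stress response genes 6 rose and 9 did not pass (9 rose when adjusted over the list alone), with PPP1R15A at 2.33-fold, DDIT3 at 2.30-fold and DDIT4 at 1.5-fold. Among the 13 NF-kB targets TNF, TNFAIP3 (1.81-fold), NFKBIA (1.51-fold) and NFKBIZ, a nuclear inhibitor of NF-kB (1.65-fold), rose and 9 genes did not pass (6 rose when adjusted over the list alone). Of the 12 matricellular genes and YAP/TEAD targets 4 rose and 8 did not pass (4 rose when adjusted over the list alone): CCN2, CCN1 (2.27-fold), EDN1 (1.93-fold) and THBS1, which encodes thrombospondin (1.62-fold, adjusted p = 0.0485). The THBS1 call ended with any 1 of the 6 arrays left out and when dim probes were kept, and NFKBIZ kept its call without 3 of them. Of the 12 TGF-beta and BMP targets TGIF1 rose (1.38-fold) and 11 did not pass (4 rose when adjusted over the list alone). Another probe of TGIF1 was at 0.27 with E2 (limma, unadjusted p = 0.063). Camera called these 7 lists upward, with adjusted p of 0.00028 or less, and all 7 held with an estimated correlation. The 12 SRF cytoskeletal targets, of which FHL2 (1.44-fold) and SRF (1.35-fold) rose and 10 did not pass (2 rose when adjusted over the list alone), had an adjusted p of 0.035, which became adjusted p = 0.117 with an estimated correlation, and FHL2 and SRF each kept their call without only 1 of the 6 arrays.

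The 2 ligands were then set against each other. Of the 61 genes that rose with OHT and the 57 that rose with E2, 47 were shared, where independent lists of these sizes would share 0.296, and 0 of the 4 and 4 falls were shared. The 3 shared genes with the largest OHT rise were CCN2 (OHT minus E2 -0.04, 95% interval -0.38 to 0.30), FOSB (0.12, -0.17 to 0.40) and ATF3 (0.11, -0.12 to 0.34). FOS differed by -0.37 (-0.64 to -0.10, adjusted p = 0.871). All 79 genes called with either ligand had the same sign with both, but the shared uninduced arrays alone gave the same sign for 76.4 of 79 genes on average, and at most 79, when simulated without effects. For 75 of the called genes the 95% interval of the difference lay within 1.5-fold. Limma called 0 genes different between OHT and E2, with a smallest adjusted p of 0.643, while 663 genes had an unadjusted p under 0.05. The 5 genes with the smallest p were SDC3 (-0.47), MSX2P1 (-0.45) and TDRKH (-0.54), each above background on 0 of 3 OHT arrays and so at least 1.15-fold, 1.11-fold and 1.20-fold higher with E2, and PLEKHA8 (0.45) and TNRC6C (0.39), with the higher mean with OHT, none of them called. PHLDA1, picked out after its values were seen, was 0.04 with OHT and 0.55 with E2, a difference of -0.50 (-0.74 to -0.26, adjusted p = 0.643), and 1 of the 17 MAP kinase feedback inhibitors, PHLDA1, was lower with OHT when adjusted over the list alone. Across the 11729 genes, which are not independent replicates, the OHT and E2 changes correlated at r = 0.69, where the shared uninduced arrays alone gave 0.501 in simulation and at most 0.524. Their covariance was 0.0166 against 0.0065 simulated, a difference of 0.01. The 3 uninduced arrays are too few to split with at least 2 on each side, so part of the excess of the 47 shared rises over independent lists may come from these shared controls. By list, the 14 heat shock genes were higher with OHT by camera (adjusted p = 0.0259, median 0.08, 0 genes called, 1 higher when adjusted over the list alone), with adjusted p = 0.743 with an estimated correlation. The doses differed, and the OHT and E2 arrays lie on different beadchips and at different positions. A dose, beadchip or position difference therefore cannot be told apart from a difference between the compounds.

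**Figure D1:**
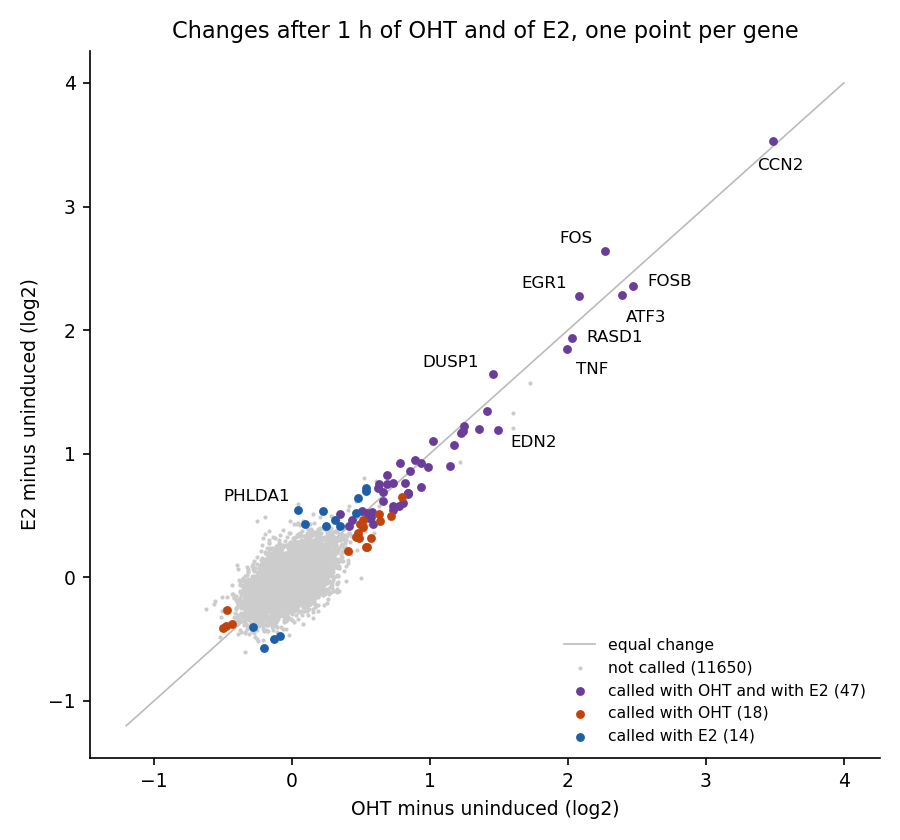
Change after OHT (x axis, log2) against change after E2 (y axis, log2) for each of the 11729 genes, with the line of equal change; colours mark the 47 genes called with both ligands, 18 called with OHT and 14 called with E2. CCN2 lies at 3.49 and 3.53, and all 79 coloured points have the same sign on both axes, which share the uninduced arrays.

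The third question was how the response to OHT differed in cells given the GPR30 antisense. FOS was 4.49-fold lower with the antisense (-2.17 ± 0.13 log2, SE; n = 3 arrays per group; adjusted p = 2.1e-07), at a log2 signal of 5.29 ± 0.06 (SD) against 7.46 ± 0.23 with OHT alone and 5.19 ± 0.19 uninduced. DUSP1, the phosphatase of MAP kinases, was 3.84-fold lower (-1.94 ± 0.10), RASD1 3.79-fold (-1.92 ± 0.11) and TNF 3.23-fold (-1.69 ± 0.15). CCN2 was 2.45-fold lower (-1.29 ± 0.16) and CCN1 1.88-fold lower (-0.91 ± 0.10). Falls were also seen for RGS16 (2.29-fold), ATF3 (2.25-fold), EDN2 (2.24-fold), FOSB (2.03-fold) and EGR1 (1.63-fold). HSPA1A, which encodes the inducible chaperone Hsp70, was 2.39-fold lower (-1.26 ± 0.18), with an SD of 0.50 over the antisense arrays. These 2 groups lie on different beadchips, so values within a beadchip are given with the gene sets. In all, 48 genes changed, 44 down and 4 up, 34 and 1 of them at least 1.5-fold, and 1667 genes had an unadjusted p under 0.05. All 48 had the arrays of the 2 groups wholly apart, which their calls favour, as did 16.4% of all genes against 10% by chance. The 4 rises were UBR1, a ubiquitin ligase of the N-degron pathway (1.57-fold), FAM114A2 (1.48-fold), TINF2, a shelterin subunit (1.40-fold), and ZSWIM5 (1.35-fold), none of which held with each array left out in turn, while 25 of the 44 falls did. Of the 44 genes that fell, 30 had been called as risen with OHT, where independent lists would share 0.229, and 14 had not been called. The same OHT arrays enter both lists. In 100 draws simulated without an antisense effect 0 genes were called lower at all, so these draws cannot show what overlap the shared arrays give. The draws also held no beadchip difference. From E2 against uninduced cells, which shares no array with this comparison, 28 of the 44 had risen, where independent lists would share 0.214. Antisense arrays B and C stood apart from the other 10 on the first principal component, with scores of 11.5 and 24.7 against -5.62 to -1.54 for the rest, and had the lowest total signals, 10445650 and 9643352. The count was 553 without antisense array A (161 up, 392 down), 29 without OHT array A and 29 without antisense array C. Without antisense arrays B and C, which leaves 1 antisense array against 3 OHT arrays, 12 genes were called. Calls were then lost for CCN2, CCN1, FOSB, EGR1 and HSPA1A, at -1.04, -0.82, -0.92, -0.67 and -0.71, and for HSPA1B, NR4A2, DUSP5, ERRFI1, TNFAIP3, NFKBIA, CXCL1 and, at -0.35, JUN, and of all these the values of HSPA1A and JUN moved by more than 1.5 times. With the median shift JUN, ERRFI1, NFKBIA, CXCL1 and the 4 rises lost theirs. The count was 151 with the other background model (29 up, 122 down), 127 without background correction (24 up, 103 down), 117 from the authors' value table, 120 with the trend and robust prior, 252 with array weights and 24 with these 2 groups alone.

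**Figure D2:**
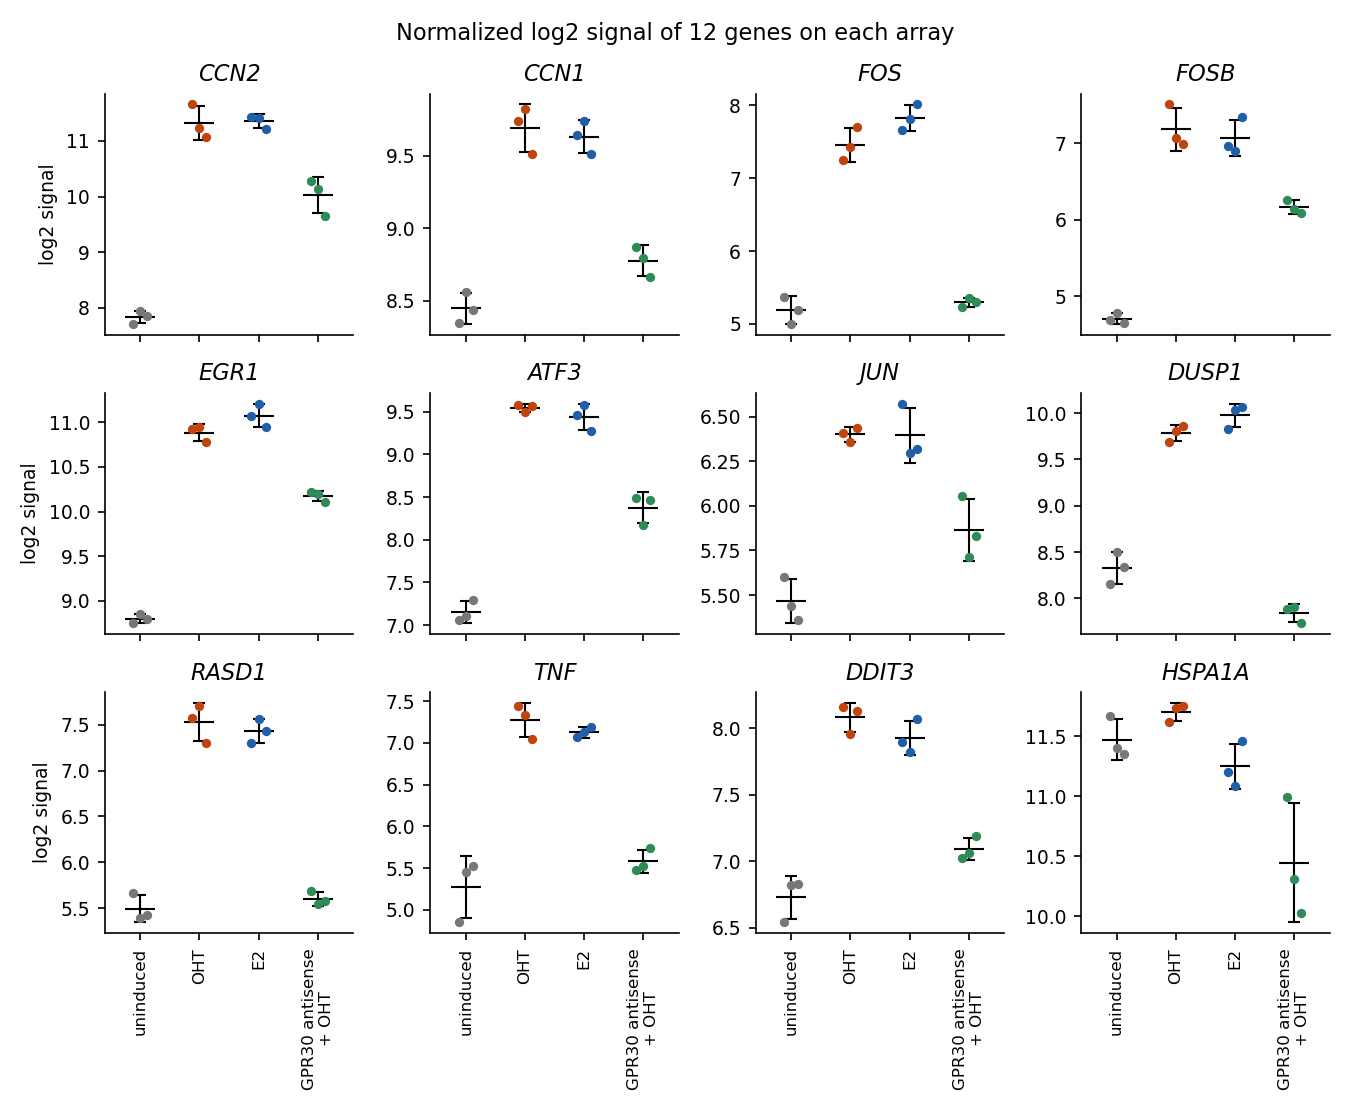
Normalized log2 signal (y axis, its range set per gene) of 12 genes on each array, for the 4 groups of 3 arrays; points are arrays, and bars give the mean and SD. FOS falls from 7.46 with OHT to 5.29 with the antisense, close to the uninduced 5.19, while CCN2 falls from 11.32 to 10.03, above the uninduced 7.83.

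Of the 21 immediate early transcription factors 10 fell with the antisense, 0 rose and 11 did not pass (13 fell when adjusted over the list alone). ZFP36, which encodes an mRNA-destabilising protein, was 1.79-fold lower, NR4A2 1.58-fold and JUN 1.45-fold. The JUN call ended when dim probes were kept and held without only 1 of the 6 arrays, those of TNFAIP3, NFKBIA and CXCL1 without 2 and those of NR4A2 and DUSP5 without 5. Among the 17 MAP kinase feedback inhibitors 4 fell and 13 did not pass (4 fell when adjusted over the list alone), among them DUSP5 (1.56-fold) and ERRFI1 (1.48-fold). Of the 13 CREB and cyclic AMP targets 4 fell, namely FOS, DUSP1, ATF3 and NR4A2, and 9 did not pass (6 fell when adjusted over the list alone). Of the 15 stress response genes DDIT3 (1.99-fold), DDIT4 (1.98-fold), PPP1R15A (1.87-fold) and ATF3 fell and 11 did not pass (adjusted over the list alone, 8 fell and 1 rose). Of the 13 NF-kB targets TNF, TNFAIP3 (1.69-fold), NFKBIA (1.45-fold) and the chemokine CXCL1 (1.40-fold) fell and 9 did not pass (5 fell when adjusted over the list alone). Of the 12 matricellular genes and YAP/TEAD targets CCN2, CCN1 and EDN1 (1.94-fold) fell and 9 did not pass (4 fell when adjusted over the list alone). Camera called these 6 lists downward with adjusted p of 0.0028 or less, and all held with an estimated correlation. Of 14 heat shock genes HSPA1A and HSPA1B fell, near-identical paralogs whose probes may share signal, and 12 did not pass (5 fell when adjusted over the list alone). That list's median was -0.02 and its mean -0.19, with an adjusted p of 0.012 that became adjusted p = 0.161 with an estimated correlation. Antisense arrays B and C, which stood apart, enter each of these list values.

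Sets of genes were followed as a whole. The 57 genes that rose with E2, chosen without the OHT arrays, had a median antisense minus OHT of -0.53, with -0.44, -0.48 and -0.52 for antisense arrays A, B and C. Of them, 52 were lower with the antisense, 28 were called lower, 0 higher, and 8, CCN2, EGR1, FOSB and ATF3 among them, were still called above the uninduced level. Medians of the 10000 matched lists of unresponsive genes, from which genes called with the antisense were left out, ran from -0.08 to 0.11. The 61 genes that rose with OHT had a median of -0.54, with 60 lower and 30 called lower. Simulated arrays with the OHT effect, no antisense effect and no beadchip difference gave -0.02 (-0.05 to 0.01). They took the larger observed OHT changes as the true ones, so they may understate the fall that choosing genes on the OHT arrays gives. The median over the 21 immediate early genes was -0.48, and over the 12 matricellular genes -0.13. Within the beadchip that holds both E2 and antisense arrays, the 61 genes had a median antisense minus E2 of -0.40 (95% bootstrap interval -0.53 to -0.32), with 56 lower. The bootstrap resampled the genes, which are not independent, and held the arrays fixed, so the interval leaves out the spread between arrays. Antisense arrays A, B and C had medians of -0.39, -0.44 and -0.41 against the E2 mean. FOS (-2.54 ± 0.13), DUSP1 (-2.13 ± 0.10), RASD1 (-1.83 ± 0.11) and CCN2 (-1.33 ± 0.16) were called lower within this beadchip, among 30 genes lower and 2 higher. Of the 44 genes that fell against OHT, 23 were called lower than E2. The sizes depended on the processing: the median over the E2 genes was -0.28 with the other background model, -0.29 without background correction and -0.27 from the authors' value table. The median over the OHT genes was -0.33, -0.33 and -0.29 under the same settings and -0.96 with the median shift. The matricellular median was -0.08 without OHT array B, -0.23 with the median shift, -0.22 over probes above background on all 12 arrays, -0.26 against E2 and -0.025 without the filter on dim probes, where the immediate early median was -0.28.

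**Figure D3:**
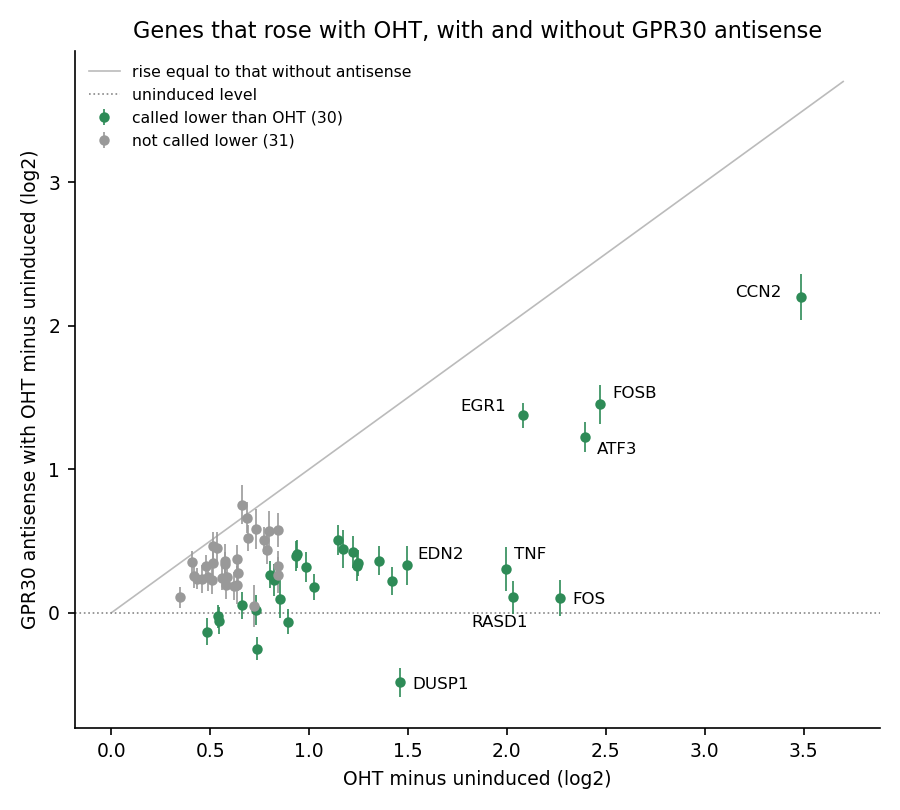
Rise of the 61 OHT genes against uninduced with OHT alone (x axis, log2) and with OHT and the GPR30 antisense (y axis, log2); bars give the SE, the solid line is an equal rise and the dotted line the uninduced level. The 30 genes called lower than OHT are green, with FOS at 0.10, DUSP1 at -0.48 and CCN2 at 2.20 on the y axis.

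Antisense-transfected cells with OHT were last compared with uninduced control-transfected cells, which differ from them in both the transfection and the ligand. CCN2 was 4.58-fold higher (2.20 ± 0.16 log2, SE; n = 3 arrays per group), FOSB differed by 1.45 ± 0.14, EGR1 by 1.38 ± 0.09 and ATF3 by 1.22 ± 0.11. Among genes named here after their values were seen, KLF2, an endothelial and immune transcription factor (0.75 ± 0.14), and NCOA7 (0.66 ± 0.11) were also higher. HSPA1A (-1.03 ± 0.18), QPRT, an enzyme of NAD synthesis (-0.72 ± 0.10), TXNIP, an inhibitor of thioredoxin (-0.58 ± 0.10), and RAD21, a cohesin subunit (-0.45 ± 0.08), were lower. FOS differed by 0.10 ± 0.13 (adjusted p = 0.729) and DUSP1 by -0.48 ± 0.10 (adjusted p = 0.0816). Of the 21 immediate early genes 5 were called higher and 16 did not pass (9 were higher when adjusted over the list alone), and camera called that list, the MAP kinase feedback inhibitors (0 of 17 called, 8 higher and 1 lower when adjusted over the list alone) and the stress response (1 of 15 called higher, 7 higher and 2 lower when adjusted over the list alone) upward. The stress response list lost its call, with adjusted p = 0.11 with an estimated correlation. In all, 23 genes changed, 9 up and 14 down, and 1772 had an unadjusted p under 0.05. The count was 6, 4 and 5 without uninduced arrays A, B and C, 548, 7 and 6 without antisense arrays A, B and C, 4 without antisense arrays B and C together, which leaves 1 antisense array, and 4 with these 2 groups alone. CCN2, EGR1, FOSB and ATF3 kept their calls in all of these, while QPRT lost its call without uninduced array B. KLF2, NCOA7, HSPA1A, TXNIP and RAD21 kept theirs without only 1 of the 6 arrays, antisense array A, and these 5 and QPRT lost theirs without antisense arrays B and C and with the 2 groups alone. With the median shift KLF2 and NCOA7 lost theirs, as did KLF2, HSPA1A and TXNIP without the filter. The count was 216 with the other background model, 175 without background correction, 150 from the authors' value table, 176 with the trend and robust prior, 392 with array weights, 15 without the filter, 49 over probes above background on all 12 arrays and 1142 with the median shift (4 up, 1138 down), which moved the median of all genes to -0.23.

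Lists outside the immediate early, signalling and stress groups held few or no called genes. Of 15 classical nuclear estrogen receptor targets 0 changed in any of the 3 main comparisons (also 0 when adjusted over the list alone). Their median was -0.09 with E2, where camera gave an adjusted p of 0.064, and TFF3, a trefoil peptide gene induced through the nuclear receptor, was at -0.25 ± 0.11 (adjusted p = 0.566). IRF1, an interferon-induced transcription factor, rose with OHT (1.74-fold) and was the 1 called gene among 16 interferon-stimulated genes. Its call held without only 2 of the 6 arrays, and with E2 it was at 0.65 ± 0.14 (adjusted p = 0.061). CYP1A1, the standard target of the aryl hydrocarbon receptor, was at -0.24 ± 0.16 with OHT and -0.52 ± 0.16 with E2 (adjusted p = 0.816 and 0.266), and 0 of 6 genes of that list were called (1 rose and 1 fell with E2 when adjusted over the list alone). Among 5 ERBB receptors and ligands, 8 NRF2 targets, 13 cholesterol synthesis genes, 11 p53 targets, 22 cell cycle genes, 13 hypoxia genes and 12 luminal epithelial markers, 0 were called in the 3 comparisons and camera called no list. Adjusted over the list alone, 2 hypoxia genes rose with OHT, and 2 p53 targets, 1 NRF2 target, 1 cholesterol gene and 1 interferon-stimulated gene rose with E2. With the antisense, again adjusted over the list alone, 3 cholesterol genes, 3 hypoxia genes, 1 p53 target, 3 SRF cytoskeletal targets and 3 TGF-beta and BMP targets fell. Camera gave the latter 2 lists an adjusted p of 0.245 each, and 0 of their genes were called. For other cell types, 0 of 5 measured endothelial markers changed (1 rose with the antisense when adjusted over the list alone), and the measured receptor genes (2), fibroblast markers (2) and leukocyte marker (1) were too few for a list test and were not called.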

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

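The comparison within the second beadchip, the matched gene lists, both tests of the share of the rise left and the fits without antisense arrays B and C were chosen only after the result was seen. The set of genes that rose with E2 was set out beforehand, but the limits for using it against selection on the OHT arrays were set afterwards. Whether the design holds uninduced antisense arrays was set out beforehand.

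Probes without a single gene symbol, which no comparison by gene uses, also responded. Of 6107 such probes, limma called 5 with OHT and 6 with E2, all higher, 1 with the antisense against OHT, lower, and 4 with the antisense against uninduced cells, all higher. The largest change, in the same probe for both ligands, was 2.19 ± 0.13 (SE) with OHT and 2.42 ± 0.13 with E2.

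The genes that rose with OHT were lower in the antisense arrays as a set. Within the beadchip that holds both antisense and E2 arrays, the 61 genes lay at a median of -0.40 against E2, given at another dose. This argues against a beadchip difference as the whole account only if E2 and OHT raised these genes alike. Their likeness (median E2 minus OHT -0.09) was itself measured across the beadchips, so a beadchip difference stays open. The E2 and antisense arrays also lie at different positions. The matched lists do not test a lower overall signal of the antisense arrays, although 0 of 10000 had a median as low as the genes that rose with E2. Quantile normalization had already evened out overall signal, and genes called with the antisense were left out of the lists. Antisense array A had a total signal of 12329088, above the OHT arrays (11075695 to 11783838), and a median of -0.44 over the E2 genes. A lower overall signal is therefore argued against for that array only. Selection of genes on the OHT arrays is argued against by the median of -0.53 in the E2 genes. It stays open whether the antisense lowered the uninduced level of these genes, because 0 uninduced antisense arrays are in the design, and whether another effect of the antisense transfection than on GPR30, whose mRNA was below background, contributed, which was not tested. With these points open, a dependence of these rises on GPR30 may account for the pattern but is only a hypothesis.

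The share of the OHT rise left with the antisense differed between genes. It is a ratio of log2 differences from uninduced, so it is not the share of the added transcript. CCN2, for example, was 11.2-fold above uninduced with OHT and 4.58-fold with the antisense. Shares on the linear scale were not tested. Over the 16 genes that rose more than 2-fold with E2, the log2 share ran from 66.0% ± 3.7 (SE) for EGR1, 63.0% ± 4.0 for CCN2, 58.7% ± 4.8 for FOSB and 51.2% ± 3.9 for ATF3 down to 5.27% ± 5.45 for RASD1, 4.59% ± 5.44 for FOS and -33.2% ± 8.4 for DUSP1. Spread between arrays of a group around one common share, 33.0%, is argued against by a heterogeneity statistic of 387.67, where 1000 simulations gave at most 38.5. These simulations and the SEs held no beadchip difference, although the antisense arrays lie on the other beadchip from the OHT and uninduced arrays. The statistic therefore does not argue against one common share with beadchip differences that vary by gene. Compression that follows the OHT signal level is argued against by 227.23 after such a share was fitted. There 1000 simulations, again without a beadchip difference, gave at most 33.1. Compression that follows the uninduced or antisense level was not fitted, and FOSB was at 4.71 and FOS at 5.19 uninduced. A second input to EGR1, CCN2, FOSB and ATF3 that the antisense does not reach could give these differing shares. An antisense effect on the uninduced level of some genes could also give them, and neither was tested.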

How the results depend on the processing

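Fits without antisense arrays B and C and the comparison with E2 within a beadchip were tests chosen only after the result was seen. No called gene named for OHT, E2 or the antisense against OHT changed sign under any setting run for these 3 comparisons. Over settings other than leaving out 1 array, the named genes kept their side of the threshold 742 times, lost their call 26 times and gained one 6 times for OHT, 730, 19 and 20 times for E2, and 729, 30 and 16 times for the antisense against OHT. Where counts moved, the cause was not tested, except that a fold minimum can only lower a count. Without antisense arrays B and C that group holds 1 array, assumed to vary like the other groups. The beadchip could not be fitted as a block, since each group lies on 1 beadchip. Dim signal limits GPER1 and ESR1, below background on all 12 arrays.

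OHT called 33 genes with the median shift and 43 with the fold minimum, against 65. E2 called 106 with the other background model, 99 without background correction, 105 from the authors' value table, 103 with the trend and robust prior, 95 with array weights, 38 with the median shift and 38 with the fold minimum, against 61. The antisense against OHT called, under the first 5 of these settings, 151, 127, 117, 120 and 252 genes, 24 with 2 groups alone and 12 without antisense arrays B and C, against 48. The antisense against uninduced cells called, under the same 5 settings, 216, 175, 150, 176 and 392 genes, 1142 with the median shift, 15 without the filter, 49 over probes above background on all 12 arrays, 11 with the fold minimum, 4 with 2 groups alone and 4 without antisense arrays B and C, against 23. OHT against E2 called 0 under every setting run. For the antisense against OHT, fry in either direction called 14 lists, against 7 by camera.

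Antisense medians stayed below 0 under every setting. Over the immediate early genes (-0.48) the median was -0.33 with the other background model, -0.36 without correction, -0.28 without the filter, -0.33 from the value table and -0.38 without antisense arrays B and C. Over the matricellular genes (-0.13) it was -0.23 with the median shift, -0.025 without the filter, -0.22 over probes above background on all arrays and -0.26 against E2. Over the genes that rose with E2 (-0.53) it was -0.28 with the other background model, -0.29 without correction, -0.75 with the median shift, -0.41 with cyclic loess, -0.39 over probes above background on all arrays, -0.27 from the value table and -0.38 without antisense arrays B and C. Over the genes that rose with OHT (-0.54) it was -0.33, -0.33, -0.96, -0.36, -0.29 and -0.40 under the same settings without the loess, and -0.73 and -0.64 when genes were chosen without OHT array A or B and the antisense set against that array.

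With each array left out in turn, counts ran from 45 to 53 for OHT, 39 to 48 for E2, 29 to 553 for the antisense against OHT and 4 to 548 against uninduced cells. The antisense medians ran from -0.52 to -0.37 over the immediate early genes, -0.19 to -0.08 over the matricellular genes, -0.66 to -0.38 over the E2 genes and -0.62 to -0.49 over the OHT genes, and the correlation of OHT and E2 changes from 0.63 to 0.729.

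Whether the replicate letters mark a shared culture or day is not given in the sources used here, and the main fit, set out beforehand, did not take them as pairs. Of 18 same-letter pairs 2 had deviations that correlated over 0.1, which does not rule out a shared culture or day. The median was 0.033 for the same letter and -0.023 for other letters, but deviations sum to 0 within a group, so these medians are not independent. The highest was 0.21, and 11 of 12 arrays were closest to their own letter, a hint of shared letters from the data and not the design. With the letter as a replicate block, 62 genes were called for OHT, 65 for E2, 55 and 27 for the antisense against OHT and against uninduced cells and 0 for OHT against E2, and 58 of 65, 56 of 61 and 46 of 48 calls of the main comparisons were kept.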

Other observations

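All tests of the metallothionein pattern were chosen only after the result was seen, while the counts over other splits of the arrays were set out beforehand.

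Of the 44 genes lower with the antisense than with OHT alone, 14 had not been called with OHT, and they are named here after their values were seen. They include MYC, a transcription factor of cell growth (-0.48 log2), ZFP36L1, an mRNA-destabilising protein related to ZFP36 (-0.73), CXCL1, a chemokine (-0.49), NPR1, a receptor for natriuretic peptides (-0.61), TLR9, a sensor of unmethylated DNA (-0.63), and HSPA1A and HSPA1B (-1.26 and -0.60). GADD45GIP1 (-0.76), SNAPIN (-0.62), MMS22L (-0.62), ZBTB10 (-0.56), VAPB (-0.54), HDX (-0.50) and CPEB4 (-0.46) complete them, and MYC (0.26 with OHT, adjusted p = 0.460) and CXCL1 (0.36, adjusted p = 0.109) rose with OHT when adjusted over their lists alone. Another probe of VAPB had the opposite sign, 0.37. Against E2, within a beadchip, MYC (-0.62, adjusted p = 0.00582) and ZFP36L1 (-0.59, adjusted p = 0.0428) were called lower, and the other 12 were not, HSPA1A (-0.80, adjusted p = 0.126) and HSPA1B (-0.21, adjusted p = 0.358) among them.

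Metallothionein genes, which encode metal-binding proteins, were far higher in 1 array of each ligand group. The median of MT1F, MT1G, MT1X and MT2A lay 3.17 log2 above the mean of the other 2 OHT arrays in OHT array B and 3.10 above that of the other 2 E2 arrays in E2 array B, and MT1F was at 5.49, 8.94 and 4.66 in OHT arrays A, B and C and at 5.14, 8.65 and 4.85 in E2 arrays A, B and C. These near-identical paralogs may share probe signal, and none was called with either ligand. MT1X was also higher in array A than in array C, at 9.39 and 8.73 with OHT and 9.13 and 8.25 with E2. Uninduced arrays ran from 8.31 to 8.53 for it. A beadchip or position effect is argued against by the arrays at the same positions of the other beadchip. Their highest median, against the other arrays of their own groups, was 0.18. A condition shared by all cultures lettered B is argued against by a lowest median of -0.084 in uninduced B and antisense B. Both tests use these same 2 arrays, so they are not separate evidence. Zinc or another metal reaching the cultures of OHT array B and E2 array B is a candidate explanation that stays open. In them the zinc exporter gene SLC30A1 was 1.73 and 1.80 above the mean of the other 2 arrays of its group, and the importer gene SLC39A10 was at -0.90 and -1.12. However, these genes were picked from the same arrays, and SLC39A10 was also at -1.08 in antisense array C against the other 2 antisense arrays.

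The 6 arrays of each comparison can be split into groups of 3 in 10 ways, too few for a share under 0.05. In fits to the 2 groups alone, the real split called 62 genes for OHT, 64 for E2, 24 for the antisense against OHT and 4 for the antisense against uninduced cells, where the highest of the other splits called 0, so 1 of 10 splits was as large in each. For OHT against E2 the real split called 0, as did the other splits, so 10 of 10 were as large.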
